A study of Drosophila melanogaster with 4 samples.

How the data were processed

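Cap analysis of gene expression (CAGE) reads the 5' ends of capped RNAs, so that each read, called a tag, marks a transcription start site and its strand. Total RNA came from testes of Drosophila melanogaster, with 10 µg of RNA from 150 pairs of testes stated for each library. Flies were crossed at 25 °C for 3 days, eggs and young larvae were moved to 29 °C, and males were dissected at an age of 0 to 2 days, per the labels' protocols. The control group carried bamGAL4 alone, a driver that switches on transgenes in late spermatogonia. The knockdown group added RNA interference against kmg. Each group had 2 libraries, 4 in all. The protocol named in the labels prepares libraries without PCR amplification. The control libraries were read as single reads of 76 bp, and the knockdown libraries were read at 150 bp in pairs with read 1 used, per the labels. Read length therefore differed exactly where the genotype differed, and the effects of these cannot be told apart.

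Trim Galore 0.6.6, STAR 2.7.11b, bedtools and the genome builds BDGP6 and dm6 are named in the submitters' processing notes, without their roles. The caller that joined start positions into clusters is not given in the sources used here. The deposited data were 3 tables: the clusters of start positions of each group, and a consensus list over both groups. The column of cluster levels is named TPM, for scaled tags, per the file headers, but it held whole numbers summing to 56519714 in control and 34975246 in the knockdown, so the deposited values were treated as raw tag counts. The number of start positions per cluster is likewise deposited as a whole number. The interquantile width deposited by the authors is another measure, the distance in bp between a lower and an upper quantile position of a cluster's tags. Clusters made of a single position held at least 50 tags, and so did every consensus cluster. The value in the consensus table equalled the sum of the groups' cluster counts exactly in 83.0% of the 43632 consensus clusters.

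Each table gave 1 pooled value per group over its 2 libraries, and no value per library was analysed here. The data therefore hold no replicate spread. No p-value was computed, every difference below compares these pooled libraries, and nothing below has a replicate check. The plan fixed before the data were examined named a fixed rule of size for this case, and that rule was used. It had taken the values as already scaled. Since they were counts, they were scaled here to tags per 1000000 tags in the group's clusters, written TPM below. Intervals are 95% intervals, Wilson for shares and exact binomial for ratios of counts. Intervals and floors cover counting error only. A count of 0 was given a floor of 3 tags over the group's pooled libraries, 0.0531 TPM in control and 0.0858 TPM in the knockdown. Tags that a consensus cluster held beyond the called clusters of both groups could come from either group; where these were more than 3, they were used as the floor.

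Tag clusters of each group were assigned to the consensus clusters they overlap on the same strand. Consensus clusters with at least 1 TPM in either group were tested. The change was log2((knockdown + 1) / (control + 1)), a scale that understates changes of low clusters. Clusters at 2 or above (4-fold) were called gained, those at -2 or below were called lost, and other clusters called in both groups were called shared. Each dominant start position was placed on the gene models of Ensembl release 115, which use the dm6 coordinates: at an annotated transcription start site (TSS) within 100 bp on the same strand, or else in a 5' UTR, coding exon, 3' UTR, noncoding exon or intron, antisense to a gene, or between genes. A cluster was sharp at an interquantile width of 10 bp or less. Shares of gained, shared and lost clusters were set against 10000 random sets of consensus clusters (1000 for median widths) matched on mean level in 20 bins. These percentiles describe the libraries and are not tests across clusters. A tag cluster had a partner if any cluster of the other group overlapped it on the same strand. A dominant position was shifted when it lay over 10 bp away in the other group, among matched clusters of at least 5 TPM in both.

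Gene levels were sums over the clusters assigned to a gene, with a filter of 1 TPM in either group. Each cluster was assigned to 1 gene at most, so tags of a promoter that genes share can be credited to the other gene. There were 16 gene lists, fixed before the data were examined: Kmg and partners of the NuRD chromatin complex; testis transcription regulators of the tMAC and tTAF complexes; late spermatocyte and spermatid genes; early germline; cyst cells; hub; muscle; neuron; fat body; hemocyte; accessory gland and ejaculatory bulb; ribosomal proteins; heat shock; antimicrobial peptides; patterning regulators; and visible marker genes. A list's median log2 ratio was given its percentile among 10000 random gene lists of its size matched on mean level, and a list outside the range from 2.5 to 97.5 was said to stand apart. Where a list held genes with 0 tags in a group, its median is also given without a pseudocount and with low counts raised to the floor, written as with floors. In the late spermatid list, 1 symbol matched no gene. Named genes followed a rule fixed at the same time. The rule took kmg, Mi-2 and simj, the 12 genes with the largest rise and the 8 with the largest fall of a cluster of at least 10 TPM, up to 4 members with the largest change of each list that had a member past 4-fold, and the 5 largest gained clusters off annotated TSSs. Other names are said to be chosen after their values were seen.

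The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Tags were simulated for the comparison of knockdown and control, with counting (Poisson) noise alone and no spread between libraries. Of 43632 clusters, 100 were raised and 100 lowered 8-fold. The rule recovered 100% of the raised and 95% of the lowered clusters, with 0 false calls. Counting noise alone can hardly pass the 4-fold rule, so this gives no rate of false calls for the real libraries. Random sets with no true difference stood apart in 5.1% of draws. That check compared shares of sets and not medians of gene lists, so it gives no rate of false calls for the lists. A single unchanged list lay at percentile 31. Alternatives were pseudocounts of 0.5 and 3 TPM, no filter or a filter of 5 TPM, a rescaling by the median ratio of clusters called in both groups, size rules of 2-fold and 8-fold, other overlap rules, windows and widths, and the strongest cluster of a gene alone. Sequence elements of core promoters were not analysed here.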

Results

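CAGE of adult testes was used to compare start sites between control males and males with knockdown of kmg in the germline. Kmg (Kumgang) is a zinc finger protein of spermatocytes that works with the chromatin remodeler Mi-2. The series asks whether a complex with Kmg keeps cryptic promoters silent as germ cells differentiate. The pooled control libraries held 56519714 tags in 32731 tag clusters, and the pooled knockdown libraries held 34975246 tags in 57330 tag clusters. The 100 largest clusters took 30.8% of the control tags and 19.9% of the knockdown tags. There were 2 libraries per group, pooled in 1 value, so no difference below has a replicate check. Each group also had its own read length.

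The kmg gene, the target of the knockdown, stood at 48.5 TPM in control and 11.6 TPM in the knockdown, 4.19-fold lower. The labels do not say which part of kmg the interference targets. The log2 ratio of -1.98 just missed the 4-fold rule, and it passed at -2.62 after rescaling. Most kmg tags came from a cluster at chromosome 2L from 13160650 to 13160721, which the annotation places in an intron, with 46.7 TPM in control and 11.5 TPM in the knockdown. Its cluster at an annotated TSS held 97 control tags and 3 knockdown tags, a ratio of 0.050 (counting interval 0.0101 to 0.150). Mi-2 was at 33.5 TPM in control and 16.5 TPM in the knockdown, a log2 ratio of -0.98 that did not pass the rule. The gene simj, which encodes a p66 subunit of NuRD, rose from 9.27 to 118 TPM, 12.8-fold (counting interval 11.6 to 14.0). The simj rise came mostly from a coding-exon cluster on chromosome 3L from 10688301 to 10688537, at 0.407 TPM in control and 95.8 TPM in the knockdown. Of the 8 measured genes of the Kmg and NuRD list, 1 rose and 0 fell. The list's median log2 ratio was 0.15, at percentile 13.7 of matched random lists. MTA1-like, another NuRD gene, was at 18.0 TPM in control and 62.2 TPM in the knockdown and did not pass the rule.

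The scale of the levels differed between the groups. Over the 25902 consensus clusters called in both, the median log2 ratio of knockdown to control was 0.71, or 1.64-fold, on the TPM scale. The median over all 12398 measured genes was 0.65, and it was -0.02 after rescaling by the clusters called in both groups. Changes of gene lists are therefore given beside the values of matched random lists or this median.

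Start sites called in the knockdown alone far outnumbered those called in control alone. Of the 57330 knockdown tag clusters, 27047 had no control partner, 47.2% (95% Wilson interval 46.8 to 47.6). Of the 32731 control tag clusters, 1926 had no knockdown partner, 5.88% (5.63 to 6.14). Knockdown clusters without a partner held 11.2% of the knockdown tags, and control clusters without one held 0.380% of the control tags. The control was sequenced more deeply. Restricted to tag clusters of at least 10 TPM, 17.7% of knockdown clusters and 0.620% of control clusters lacked a partner.

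Of 43134 tested consensus clusters, 14262 were gained and 1559 were lost. Gained clusters held 24.3% of the knockdown tags and 0.974% of the control tags. Lost clusters held 16.8% of the control tags and 2.09% of the knockdown tags. Gained clusters made up 90.1% of the changed clusters, and 78.6% after rescaling, with 8941 gained and 2433 lost. A level of 100 TPM or more in either group was reached by 290 gained and 322 lost clusters. In 8353 gained clusters, 58.6%, no control cluster had been called at all. A pseudocount of 0.5 TPM gave 23268 gained clusters and 3 TPM gave 5612.

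**Figure D1:**
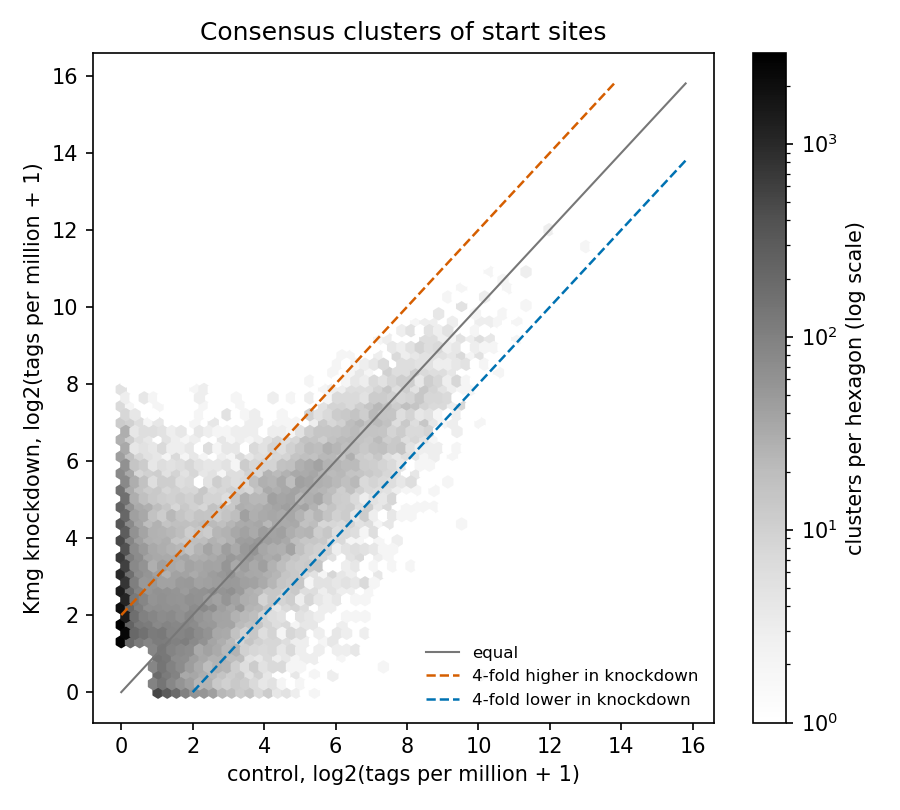
Hexagonal density plot of the consensus clusters, with log2(TPM + 1) in control on the horizontal axis and in the Kmg knockdown on the vertical axis; shading gives the number of clusters per hexagon on a log scale. The dashed lines mark the 4-fold rule, with 14262 gained clusters at or above the orange line, many of them at the left edge with no control tags, and 1559 lost clusters at or below the blue line.

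The gene CG16815 had the largest rise of any named cluster. Its coding-exon cluster on chromosome 2L from 13229955 to 13230261 went from 0 control tags to 369 TPM, at least 6956-fold higher over the floor. Other coding-exon clusters with 0 control tags were in CG32374 (276 TPM, at least 5203-fold), in Osi22, an Osiris family gene (236 TPM, at least 4439-fold), and in tld, the protease tolloid (166 TPM, at least 3128-fold). The coding-exon clusters of CG32413, CG5550, Hel89B and Acp32CD rose as well, from 0.336, 0.0708, 0.584 and 0.0885 TPM to 260, 184, 258 and 176 TPM. An intronic cluster of Pka-C1, the catalytic subunit of protein kinase A, rose from 0.0708 to 170 TPM. Of the 12 genes with the largest rises, 3 rose at an annotated TSS. These were Obp73a, an odorant-binding protein gene (0 to 227 TPM, at least 4269-fold), and the long noncoding RNA genes lncRNA:CR45672 (0 to 235 TPM, at least 4428-fold) and lncRNA:CR44146. The last had 3 control tags and 7407 knockdown tags, a ratio of 3990 (counting interval 1365 to 19352).

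Ordered by knockdown level, the largest gained cluster off annotated TSSs lay on chromosome 4 from 1279262 to 1279333 on the minus strand. It fell in no gene and inside an annotated HeT-A element, a telomeric retrotransposon, and rose from 5.31 to 782 TPM. The next were coding-exon clusters: CG33342 on chromosome 3R from 24377057 to 24377272 (2.44 to 484 TPM), CG30428 on 2R from 25253645 to 25253889 (72.1 to 442 TPM), the CG16815 cluster, and CG14655 on 3R from 4777943 to 4778187 (5.48 to 342 TPM). The CG30428 cluster did not pass the rule after rescaling, at 1.89.

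The 8 genes with the largest falls lost clusters at annotated TSSs. The values here are those of these single clusters and not sums over the gene. CG6628 fell from 1133 to 0.429 TPM, CG32457 from 973 to 0.315 TPM, CG42827 from 414 to 0.686 TPM and vig, which encodes a protein of the RNA-induced silencing complex, from 242 to 1.26 TPM. CG17917 and CG5265 had 348 and 174 TPM in control and 3 tags each in the knockdown, ratios of 0.000247 (counting interval 5.08e-05 to 0.000721) and 0.000492 (0.000101 to 0.00144). The neighboring genes scpr-A and scpr-C fell from 3153 to 9.01 TPM and from 13518 to 42.1 TPM. They are near-identical copies that can share reads, so the split of tags between them is uncertain.

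Gained clusters lay mostly away from annotated promoters. Of the gained clusters, 93.5% (93.0 to 93.9) had a dominant start off annotated TSSs, against 47.4% (46.7 to 48.1) of shared and 34.6% (32.3 to 37.0) of lost clusters. Random sets matched on level to the gained clusters had a median of 71.4% and a highest value of 72.2%. Coding exons held 35.4% of gained clusters and 15.4% of shared ones. Antisense positions held 24.7% and 8.19%, introns 14.0% and 8.71%, and regions between genes 13.7% and 5.31%. Gained clusters at annotated TSSs numbered 932, or 6.53%. With a window of 500 bp for annotated TSSs, 78.1% of gained clusters still lay off them.

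**Figure D2:**
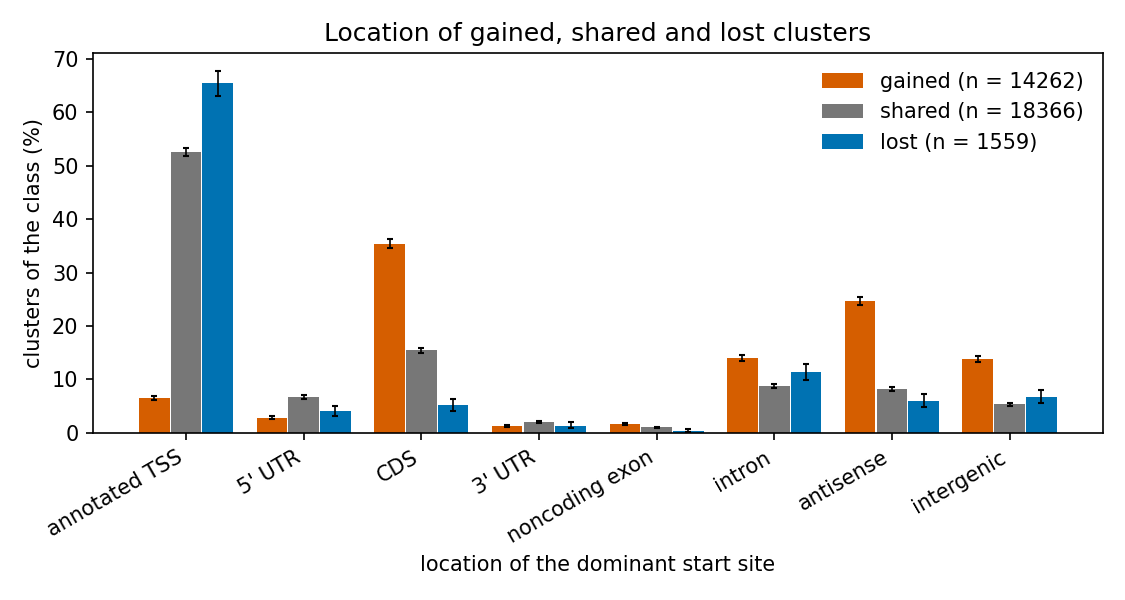
Bar chart of the location of dominant start sites, in percent of clusters of each class, for gained, shared and lost clusters; error bars are 95% Wilson intervals, which cover counting error only. Coding exons held 35.4% of gained and 5.13% of lost clusters, and annotated TSSs held 6.53% of gained and 65.4% of lost clusters.

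At the gene level, 5124 genes had at least 1 gained cluster off annotated TSSs. In 2975 of these (58.1%) another cluster of the gene stayed within 2-fold between groups, and in 2572 this steady cluster lay at an annotated TSS. Where the steady cluster was also required to reach 10 TPM in control, 1644 genes remained. For 1237 of the 5124 genes (24.1%), no cluster at an annotated TSS was found. Summed over clusters, 2712 of 12398 genes rose and 695 fell, so that 79.6% of changed genes rose. After rescaling, 1773 rose and 1157 fell, or 60.5%. Counted at annotated TSSs alone, a setting added after seeing the data, 778 rose and 864 fell.

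Under the 4-fold rule, gained clusters were broader than shared ones. Sharp clusters made up 7.08% (6.67 to 7.51) of gained, 18.7% (18.2 to 19.3) of shared and 28.0% (25.8 to 30.2) of lost clusters. Random sets matched to the gained clusters had 13.4%. Defined instead as having no control cluster, a setting added after seeing the data, 16457 clusters were 17.3% sharp with a median width of 38 bp, close to the shared clusters; random sets matched to them on level had 21.5%. The median interquantile width was 51 bp in clusters gained by the rule, 41 bp in shared and 34 bp in lost clusters. At 8264 matched clusters of at least 5 TPM in both groups, 61.3% kept the same dominant position, and 2446, or 29.6% (28.6 to 30.6), shifted by more than 10 bp. A shift of more than 50 bp was seen in 10.1%.

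The X chromosome carried 7.78% (7.35 to 8.23) of gained clusters and 13.8% (13.3 to 14.3) of shared clusters. Matched random sets had a median of 10.7%, and the gained share lay below all of them. Of lost clusters, 8.21% (6.95 to 9.68) were on X. The largest autosomal share was on 3R, with 27.3% of gained and 25.9% of shared clusters. Chromosome 4 carried 0.498% and the Y chromosome 0.154% of gained clusters.

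Genes of the nervous system stood apart upward. Of 19 genes of the neuron list, 13 were measured. Of these, 8 rose and 2 fell, with a median log2 ratio of 2.54 at percentile 99.2 of matched random lists. Gad1, which makes the transmitter GABA, rose from 0.336 to 33.8 TPM, 101-fold (64.1 to 168). The homeodomain gene pros (prospero) rose from 1.75 to 61.4 TPM, and brp, a protein of the presynaptic active zone, from 2.95 to 74.3 TPM. The synaptic vesicle gene nSyb fell from 65.3 to 2.14 TPM. Of the list's 18 gained clusters, 17 lay off annotated TSSs. With floors, the median was 4.65. The 3 genes with no control tags passed the filter only through the knockdown. The list no longer stood apart with a pseudocount of 3 TPM (median 1.38) or at annotated TSSs alone (6 genes, median 0.10).

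**Figure D3:**
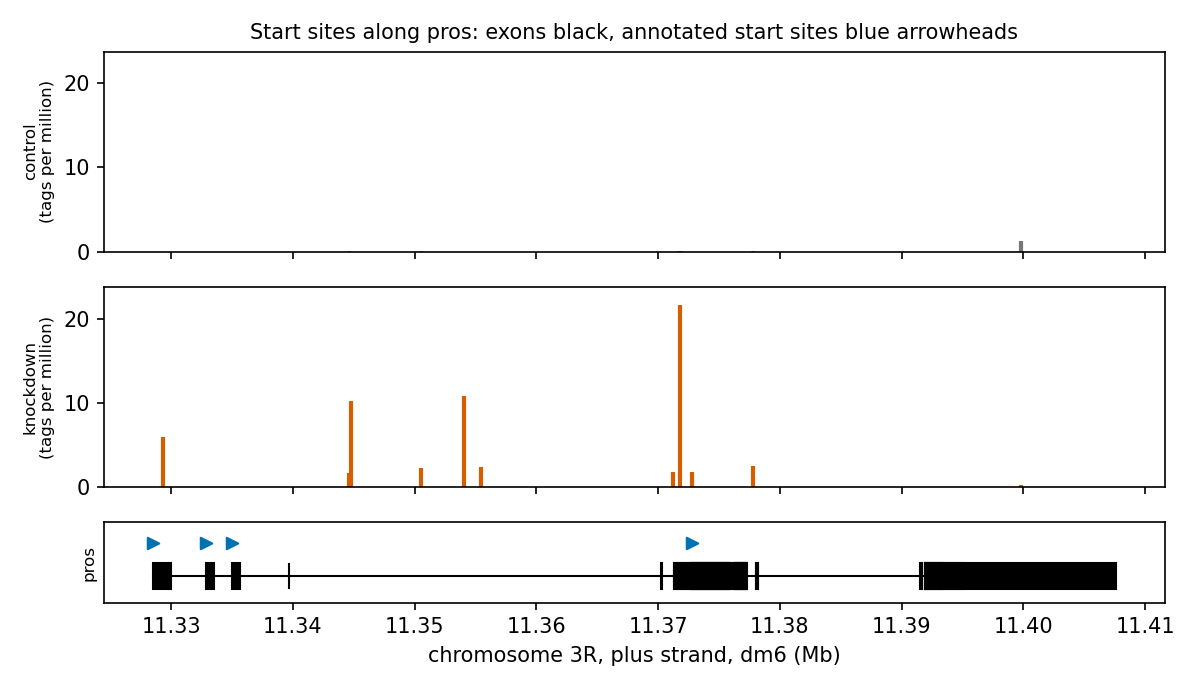
Map of the plus-strand gene pros on chromosome 3R from 11328480 to 11407627 (dm6), in Mb on the horizontal axis; vertical lines mark the consensus clusters at their dominant positions, with their height in TPM, in control (gray) and in the knockdown (orange). The tallest knockdown cluster, from 11371658 to 11371790 in a 5' UTR, reached 21.6 TPM with 0.142 TPM in control, and intronic clusters at 11344794 and 11354080 reached 10.2 and 10.8 TPM with 0 control tags.

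Developmental regulators also stood apart upward. In the patterning list, 17 of 22 genes were measured, 7 rose and 0 fell, with a median of 1.78 at percentile 99.3. With floors, the median was 3.98. The 4 genes without control tags passed the filter only through the knockdown. The gap gene kni rose from 0.548 to 26.3 TPM, and the pair-rule gene odd from 0.142 to 22.4 TPM, a ratio of 158 (79.8 to 367). The segment polarity gene en rose from 3.15 to 57.4 TPM and the Hox gene pb from 5.70 to 73.6 TPM. The list had 6 gained clusters at annotated TSSs and 14 off them. The list no longer stood apart with a pseudocount of 0.5 TPM (median 2.01) or 3 TPM (1.13), or with the strongest cluster of each gene alone (1.78). At annotated TSSs alone, a setting added after seeing the data, it did stand apart (12 genes, 4 up and 0 down, median 1.48, percentile 99.8).

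Both measured visible marker genes rose. The eye color gene w went from 11.3 to 188 TPM, with 5 gained clusters off annotated TSSs, and the body color gene y from 0.230 to 54.2 TPM at an annotated TSS. The list median was 4.71, at percentile 99.6. Fly transgenes often carry w or y as markers, so these rises can also reflect the strains used.

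The germline lists did not stand apart from random lists matched on level, with a few strong members. Of 33 measured late spermatocyte and spermatid genes, 6 fell and 1 rose. The list median was 0.11 at percentile 82.3, and -0.60 after rescaling at percentile 82.8, where 9 fell and 0 rose. Its matched random lists were themselves low, with medians of -0.16 and -0.86. Against the median of all genes, 0.65, 27 of the 33 lay below. Among all 12398 measured genes, 695 fell. The late genes were thus lower than most genes, but not lower than genes of their level. The falls included w-cup (7072 to 434 TPM), sunz (141 to 11.8 TPM), schuy (615 to 66.8 TPM), all transcribed late in spermatids, and dj, a sperm tail gene (2978 to 569 TPM). Of 12 tMAC and tTAF regulators, 2 rose and 0 fell. These were the testis-specific TAF genes Taf12L (38.1 to 603 TPM) and mia (37.5 to 347 TPM), mostly at annotated TSSs, while comr was at 4.44 and 12.8 TPM and achi at 28.2 and 65.5 TPM. The list median was 0.86 at percentile 81.7. Of 10 measured early germline genes, 2 rose and 0 fell. On the tags assigned to it, the germline helicase gene vas rose from 0.778 to 42.9 TPM through coding-exon clusters. The gene otu rose from 3 tags to 10.2 TPM, a ratio of 192 (65.3 to 937). The differentiation factor bam was at 3.79 and 17.3 TPM and the gap junction gene zpg at 3.22 and 13.5 TPM, below the 4-fold rule on the scale used. The early germline median was 1.35 at percentile 72.8.

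**Figure D4:**
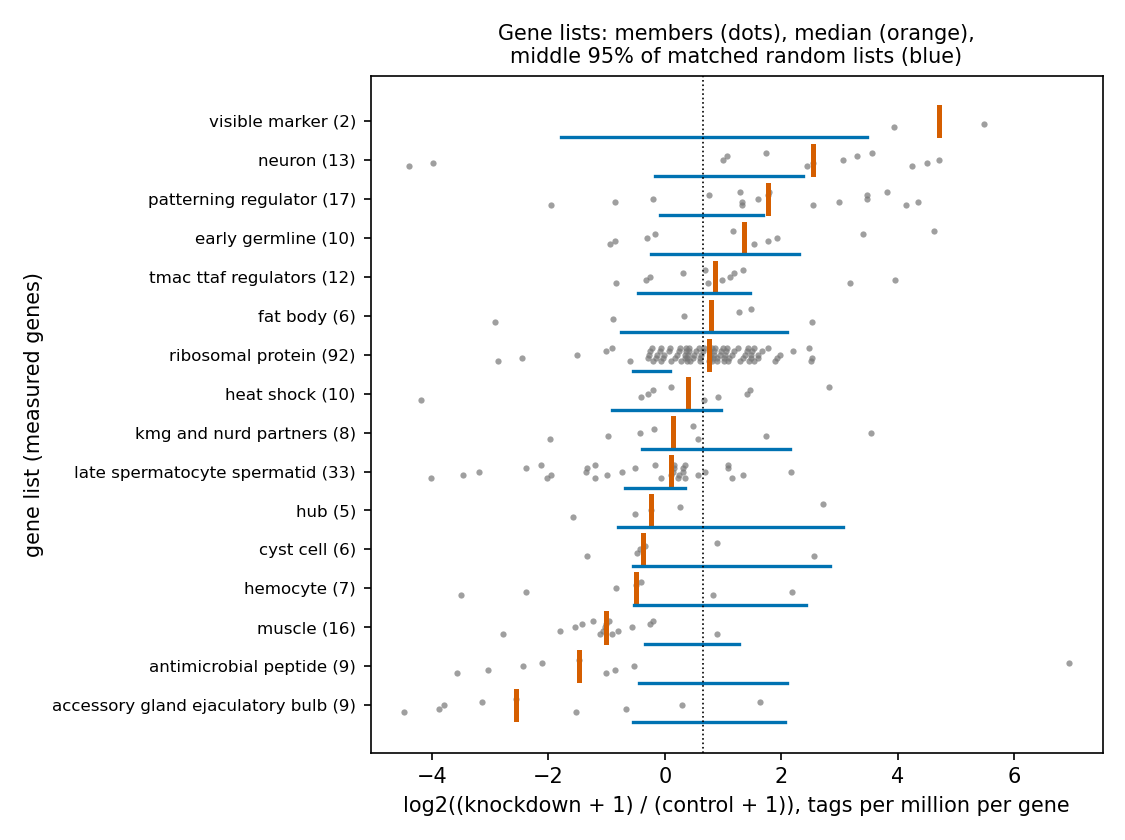
Plot of the log2 ratio of knockdown to control for the measured genes of each fixed list (gray dots), the list's median (orange bars) and the middle 95% of the medians of 10000 matched random lists (blue lines); the dotted line is the median of all genes, 0.65. The neuron, patterning, visible marker and ribosomal protein medians lay above their blue lines, and the muscle, antimicrobial peptide and accessory gland medians lay below them; after rescaling, the ribosomal protein median was 0.05.

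Muscle and accessory gland genes stood apart downward. All 16 muscle genes were measured, 1 fell and 0 rose, with a median of -1.02 at percentile 0.05, and 4 fell after rescaling. The muscle actin Act87E fell from 648 to 93.5 TPM, while Act57B was at 219 and 74.8 TPM, wupA at 121 and 34.2 TPM and TpnC73F at 31.5 and 11.1 TPM. Of 9 measured accessory gland and ejaculatory bulb genes, 5 fell and 0 rose, with a median of -2.57 below all matched random lists, and -4.17 with floors. Acp62F fell from 72.6 to 2.29 TPM, the sex peptide gene SP from 42.6 to 1.97 TPM, Acp76A from 15.5 to 0.858 TPM, and Acp26Aa from 12.8 TPM to 0 tags, at least 40.8-fold lower. Of 7 hemocyte genes, the clotting gene Hml (15.2 to 0.429 TPM) and the collagen gene Col4a1 (35.9 to 6.06 TPM) fell and the GATA factor gene srp rose (14.5 to 69.4 TPM), although srp did not pass after rescaling at 1.48. The collagen gene vkg was at 68.8 and 37.9 TPM. The hemocyte median was -0.50 at percentile 2.90, and it stood apart with the strongest cluster of each gene alone, at -1.29.

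The lists of cyst cells, hub and fat body did not stand apart. Of 6 cyst cell genes, so rose from 19.5 to 121 TPM, but not after rescaling (1.86), and 0 fell. The list median was -0.38 at percentile 4.14, with zfh1 at 6.07 and 12.2 TPM, ptc at 14.8 and 5.29 TPM and Socs36E at 13.5 and 9.41 TPM. Of 5 hub genes, CadN rose from 6.55 to 48.9 TPM, through intronic clusters, and 0 fell. The hub median was -0.23 at percentile 10.0, with Fas3 at 99.8 and 32.7 TPM, shg at 64.0 and 44.4 TPM and hh at 5.18 and 6.40 TPM. In the fat body list, 6 genes were measured. The alcohol dehydrogenase-like gene Fbp2 rose from 3.57 to 25.3 TPM, but not after rescaling (1.84), and the iron carrier gene Tsf1 fell from 135 to 16.9 TPM. Its median was 0.80 at percentile 53.0, or 1.16 with floors. Fbp1 was at 0.902 and 3.57 TPM, and the storage protein gene Lsp2 had 0 control tags and 1.80 TPM in the knockdown.

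Antimicrobial peptide genes stood apart downward. Of 9 measured genes, 4 fell and 1 rose, with a median of -1.48 at percentile 0.08, and -2.23 with floors. AttC fell from 36.9 to 2.17 TPM and AttB from 61.0 to 6.52 TPM, and DptA went from 4.44 TPM to 0 tags, at least 51.8-fold lower, a call lost with a pseudocount of 3 TPM (-1.31). CecA1 went the other way at its annotated TSS, from 0.548 to 190 TPM, 347-fold (244 to 511). AttB and CecA1 have close paralogs that can share reads.

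The 92 ribosomal protein genes had a median of 0.77, above all matched random lists, whose median was -0.24. After rescaling it was 0.05, still above all random lists, whose median was then -0.96. The median of all genes was 0.65, and -0.02 after rescaling, and 43 of the 92 lay below it before rescaling. The list thus stood above genes of its level but near the median of all genes. The rule called 4 up and 2 down, but 0 up and 3 down after rescaling. RpL41 (386 to 2232 TPM), RpL29 (95.5 to 547 TPM) and RpL37-2 (64.2 to 360 TPM) rose, but did not pass after rescaling, at 1.81, 1.79 and 1.76. RpS28a fell from 48.8 to 5.83 TPM. RpL37-2 and RpS28a have paralogs that can share reads. Of 10 heat shock genes, 1 rose and 1 fell, with a median of 0.39 at percentile 77.5, the same with floors, and -0.32 after rescaling. The small heat shock gene Hsp22 rose from 19.3 to 142 TPM, while Hsp26 was at 187 and 498 TPM. Hsp70Bb went from 17.3 TPM to 0 tags and Hsp70Ab from 14.8 to 42.7 TPM. They are near-identical copies, so tags can be assigned to either.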

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

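The alternatives at annotated TSSs alone, with uncalled tags counted as control, without transposable elements and with sharp shares of clusters having no control cluster were chosen after seeing the data. No named cluster, no named list gene past the rule and no list that stood apart reversed its direction. Over all genes called, 2 turned sign with the strongest cluster alone, and 283 of the 2260 still measured at annotated TSSs alone did, 280 of them rises, with Ubx, Hel89B, Acp32CD and CG30428 among these; 7 named genes, simj and brp included, had no value there. The balance of genes also turned there, where 778 rose and 864 fell, and the neuron list had 1 gene up and 2 down. No paired analysis was possible because the tables give 1 pooled value per group; for that reason edgeR, DESeq2, a replicate block and leaving out single libraries were not run, and core promoter elements were not run. Gained clusters (14262) and lost clusters (1559) became 23268 gained at a pseudocount of 0.5 TPM, 5612 and 864 at 3 TPM, 8941 and 2433 after rescaling, 27341 and 5001 under a 2-fold rule, and 6416 and 545 under an 8-fold rule, each following from the setting. The share without a partner was 51.1% (knockdown) and 14.5% (control) when dominant positions had to lie within 50 bp, 32.1% and 1.80% at 3 TPM or more, and 17.7% and 0.620% at 10 TPM or more. Gained clusters off annotated TSSs made up 94.9% with a 50 bp window, 78.1% with 500 bp, and 95.9% when defined by no control cluster, with 8.53% of those on X. The percent of gained clusters that are sharp was 4.96% at 5 bp or less and 4.88% at 5 TPM or more, but 17.3% for clusters with no control cluster. Dominant shifts were 10.1% beyond 50 bp and 27.9% at 20 TPM. Genes with a steady cluster numbered 1644 at 10 TPM in control. Genes that rose numbered 1762 at a pseudocount of 3 TPM, 1773 after rescaling, where 1157 fell, and 778 at annotated TSSs alone. The patterning median was 2.01, 1.13 and 1.78 at pseudocounts of 0.5 and 3 TPM and with the strongest cluster alone, and did not stand apart. The neuron median likewise was 1.38 at 3 TPM and 0.10 at annotated TSSs alone, while the hemocyte median stood apart at -1.29 with the strongest cluster or annotated TSSs alone. The cause was not tested for the list medians. Of single named genes under these settings, 401 values kept their side of the 4-fold rule, 12 newly passed it and 11 no longer did, among them pros, en, so and srp at annotated TSSs alone; of named clusters, 297 kept it, 16 newly passed and 2 no longer did. The control floor of 0.0531 TPM was a chosen value. Called control clusters held as few as 2 tags, but those of a single position held at least 50.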

Other observations

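Gene families not planned as lists, chosen after their values were seen, mostly moved with the genes above. Genes silent in control pass the filter only through the knockdown; random lists matched to the families in this paragraph had medians from 0.84 to 1.08. Of 60 measured odorant, gustatory and ionotropic receptor genes (185 annotated), 41 rose and 1 fell, with a median log2 ratio of 2.82, or 2.23 after rescaling. Ir25a, a co-receptor, went from 0 control tags to 83.5 TPM, at least 1574-fold, and Gr68a from 0 to 76.7 TPM, at least 1446-fold. The family had 41 gained clusters off annotated TSSs and 5 at them. Cuticle genes also stood high: 20 of 34 rose and 2 fell, with medians of 2.62 and 1.96 before and after rescaling, and Cpr64Ab rose from 0.0885 to 185 TPM. Osiris genes, active in insect cuticle and tracheae, had 11 of 13 up and 0 down, with medians of 3.50 and 2.86. Of 8 measured gut proteases (24 annotated) of the Jonah and trypsin families, 6 rose and 0 fell, with medians of 3.51 and 2.88. Eggshell genes, which follicle cells of the ovary express, were taken by the symbols Cp and Vm. These symbols can also take in genes that are not eggshell genes, such as Cp190. Of 7 measured genes (16 annotated), 4 rose and 0 fell, with medians of 3.54 and 2.90. The rises were those of the eggshell genes Vm26Aa, Cp38, Cp15 and Vm26Ac, and Cp38 rose from 0.177 to 21.6 TPM. The dpr and DIP cell surface genes of neurons had 13 of 24 up and 2 down, with medians of 2.13 and 1.45; dpr11 rose from 14.2 to 254 TPM. Nicotinic receptor genes had 4 of 7 up and 0 down, with medians of 2.16 and 1.47, at percentile 93.6 of matched random lists before rescaling, so they did not stand apart.

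Not every specialized family moved this way. Odorant-binding proteins had 8 of 29 up and 6 down, with medians of 1.1 and 0.51 before and after rescaling, and cytochrome P450 genes had 13 of 53 up and 8 down, with medians of 0.64 and 0.07, near those of all genes. Seminal fluid genes were taken by the symbols Acp and Sfp, which also take in adult cuticle genes such as Acp1 (0 control tags to 17.7 TPM). Of these 27 genes, 12 fell and 2 rose, with medians of -1.91 and -2.02 before and after rescaling. The fixed lists hold 7 of them. Of the other 20, 8 fell and 2 rose, with medians of -1.88 and -1.95. Mitochondrial ribosomal proteins had 4 of 73 up and 0 after rescaling, with medians of 0.81 and 0.12. Proteasome subunits had a median of 0.17, or -0.53 after rescaling, and 2 of 46 fell: the testis-specific forms Prosbeta5R1 (104 to 2.00 TPM) and Prosalpha4T1 (80.0 to 12.4 TPM). Long noncoding RNA genes had 232 of 812 up and 78 down, and 153 up and 111 down after rescaling. Clusters in HeT-A elements summed to 344 TPM in control and 1769 TPM in the knockdown, with reads of unequal length and many near-identical copies.

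The tests of scaling, of repeats, of exon fragments over all gained clusters, of nervous tissue and of somatic tissue were chosen only after the result was seen. Technical explanations were weighed for gained start sites off annotated promoters. Scaling to total tags would bring gained and lost clusters near balance once rescaled, but the ratio stayed at 3.67. Longer reads reaching into repeats were predicted to place most gained clusters there. Annotated transposable elements held 0.491% (0.389 to 0.620) of gained, 0.414% of shared and 0.962% of lost clusters. Most gained clusters thus lay outside these annotated elements. Few clusters of any class lay in them, so this share cannot decide on other effects of read length. Recapped or degraded pieces of mature mRNA would lie in sense exons, but 44.0% (43.1 to 44.8) of the 13330 gained clusters off annotated TSSs did, so such pieces cannot be the whole source. For coding-exon clusters alone this source stays open, since 7.76% (7.05 to 8.53) of 5054 were both the most upstream and the strongest start of their gene, although 34.6% were the strongest; read length and batch cannot be told apart from the knockdown, and loss of repression by Kmg stays open too, as untested.

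For the rise of the neuron list, nervous tissue carried over into the knockdown dissections was tested as a source. Such tissue would bring transcripts from annotated neuronal promoters, but 1 of the list's 18 gained clusters, 5.56% (0.988 to 25.8), lay at an annotated TSS. The interval treats clusters as independent, although the 17 off annotated TSSs came from 8 genes. Of all gained clusters, 6.53% lay at annotated TSSs, so nearly any list would give a low share. The values show only where these gained clusters started and cannot decide whether some nervous tissue was present. The abundant vesicle gene nSyb fell. Read length, some nervous tissue, and start sites opened within these genes in the germline, stay open.

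For the lower muscle and accessory gland lists, and for the hemocyte list, which did not stand apart, loss of attached tissue by 1 common factor per list was tested as the only source. Members of at least 10 TPM in control would then move alike: 14 of 15 muscle genes, 93.3% (70.2 to 98.8), lay within 2-fold of their list's median, against a median of 60% in matched random lists. The muscle list thus met the prediction, at percentile 99.95 of those lists, though other causes of a common fall would meet it too. For the accessory gland list 3 of 7, 42.9% (16 to 75), did, and for the hemocyte list 3 of 6, 50% (19 to 81), too few members to decide, so for these lists it cannot be told apart from other causes. The muscle gene outside this range was Act87E, 6.93-fold lower, while Mlc2 was 1.19-fold lower. Summed over clusters, abundant accessory gland and ejaculatory bulb markers, chosen after their values were seen, did not move alike. SP was 21.6-fold and Acp95EF 1.58-fold lower, and EbpIII stood at 222 and 274 TPM. Acp36DE was 3.25-fold higher, below the rule, although at its annotated TSS it went from 13.7 to 0.658 TPM. At annotated TSSs alone, a setting added after seeing the data, 6 of the list's 9 genes fell and 0 rose, with a median of -3.15. The test used sums over all clusters and 1 factor for 2 organs, so it cannot decide on loss of either organ. The labels name no sort of the testes, whose own sheath also holds muscle, so less sheath and an effect of the knockdown on these cells stay open, as untested.

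Hypotheses on the arrangement of gained clusters were tested against 1000 random sets matched on level. Gained clusters had another gained cluster within 1 kb in 46.4% of cases, against a median of 44.5% and a highest value of 45.9% in the random sets, a small excess. For opening in both directions, 8.55% formed a divergent pair within 300 bp, against a median of 5.41% and a highest value of 6.21%. Position at annotated TSSs, in coding exons or introns, or antisense to a gene was not matched in these sets. Antisense positions held 24.7% of gained clusters, against a median of 16.8% in random sets matched on level. The excess of pairs therefore cannot be told apart from these differences in location.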
